A study of Homo sapiens with 2 samples.

How the data were processed

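The study measured total RNA from MCF-7/ADM cells on 1-colour oligonucleotide arrays. By its name the line is a derivative of the MCF-7 breast cancer cell line with acquired resistance to doxorubicin (adriamycin). The identity of the line was not examined here. Cells received a small interfering RNA (siRNA) against SPIN1, which encodes spindlin 1, a reader of methylated lysine on histone H3, or a negative control. Per the labels' protocols, double-stranded cDNA was primed with oligo-dT, labelled with Cy3-coupled 9-mer primers and processed after the NimbleGen expression protocol. Each group holds 1 array, 2 arrays in all. Nothing gives a second culture or a repeat hybridisation, so no value here has a replicate error and no p-value was computed. The number of arrays, not counting error, limits the precision.

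The deposited table holds 1 intensity per transcript feature and array, for 38727 features. The submitters' processing notes name RMA, a method that in its usual form corrects background, equalises the arrays' distributions and summarises the probes of a feature; which of these steps were run is not given in the sources used here. The RMA version, the scanner settings and any filter on features are not given in the sources used here. The deposited intensity values run from 18.7 to 57485 in the siRNA array and from 19.5 to 57070 in the control array, so they were read as a linear scale. The sorted log2 values of the arrays differ by at most 0.13, as between arrays normalized to a common distribution. Normalization of this kind removes any shift common to all genes. No detection call came with the values.

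Features are RefSeq or GenBank accessions. The platform's gene table named 15752 of them, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCh38.p14. Another 582 were named through their unversioned RefSeq accession. No feature had several genes, and 22393 stayed unnamed here. No coordinates of features were used because the array's genome build is not given in the sources used here. The genomic span of genes entered only a comparison of dim genes under Other observations. The 16334 named features cover 14962 genes, of which 13852 rest on 1 feature. Probe sequences were not used here, so cross-hybridisation between close paralogs could not be examined.

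Intensities were converted to log2, a gene's value was the median over its features, and the difference was siRNA minus control. The median was taken in each array separately, so with 3 or more features a difference can mix features. This held for TARBP2 (0.37, with 0.24 and 0.22 in listed features) and ITGB4 (-0.44, with -0.43 and -0.08). Counts of genes differing 2-fold were taken over the brighter genes, the 7481 genes whose mean log2 intensity over both arrays was at or above the median of all genes, 7.92 (a linear intensity of 243). The others are called dim or dimmer below. As a yardstick in place of a replicate error, each gene was set against the 500 genes nearest in mean intensity. Their robust SD (1.4826 times the median absolute deviation), called the local spread below, contains real differences as well as noise. A set of 34 gene lists was fixed before the data were examined, among them a list of 4 genes remembered from the study's publication, which were probably chosen on these arrays. The median of each list was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean intensity. The resulting percentile describes these arrays and is not a test of the conditions. By chance 1.7 of 34 lists would lie outside the central 95% if the genes within a list differed independently. Members of a real list may differ together, and then more lists can lie outside. The 281 olfactory receptor genes, which serve smell and have little reason to be active in this line, were used after the data were seen as an empirical guide to background. For their mean log2 intensities over both arrays, put on the linear scale, the median was 70.6 and the 95th percentile 269. For a value in 1 array the guide is approximate, since these genes were lower in the siRNA array (median log2 difference -0.53). It may also be too low for some features. The mean log2 intensity was 6.29 for olfactory receptor and 7.51 for keratin-associated protein genes, and KRTAP21-2 stood at 11.2. Whether these values are background could not be examined, so a value above 269 is not thereby shown to come from its gene.

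Named genes were chosen by a rule fixed before the data were examined. It takes the SPIN family, the 12 highest and the 12 lowest differences among the brighter genes, the 4 remembered genes, up to 4 brighter members per list with the largest absolute difference, and each member past 2-fold in the drug metabolism and transporter lists. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were the treatment of several features per gene, the signal filter, the fold threshold, centring, removal of a lowess trend (fraction 0.3), a second quantile normalization and a pseudocount of 79.3, the 25th percentile of the linear signal. The counting and list procedures were tested on simulated data with the means and local spreads of all 14962 genes for the comparison of siRNA with control. Of 200 brighter genes changed 3-fold, 95% passed 2-fold, together with 85 unchanged genes. Of 200 lists of 25 genes, drawn at random with independent noise, 98% lay outside the central 95% when shifted by 0.5 on the log2 scale and 4% when not shifted. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.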

Results

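Gene expression was profiled in MCF-7/ADM cells after transfection with SPIN1 siRNA or a negative control, with 1 array per group. The arrays had close distributions, with median intensities of 230.4 in the siRNA array and 228.6 in the control array. Over 14962 named genes their log2 intensities correlated with r = 0.96, a correlation across genes, which are not independent replicates. The SD of the log2 difference between the arrays was 0.79 in the lowest decile of mean intensity and 0.27 in the highest. Without replicates, differences are given below as values with the spread of genes of similar intensity and without error or p-value. Where a value lies under 269, the 95th percentile of olfactory receptor genes taken as a guide to background, the difference is not an exact size. Among brighter list members named below without intensities, this holds for XDH, GSR, NOTUM, GFRA1, HMMR and NCAPG. It also holds for SLC29A2, SLC2A3, PIK3CA, PRMT6, CYP1A2 and CYP51A1.

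The targeted gene was considered first. SPIN1, the histone methyl-lysine reader that the siRNA was aimed at, had an intensity of 385 in the siRNA array and 604 in the control array, 63.7% of control (log2 difference -0.65). The direction matched the label of the siRNA array. The local spread at this intensity was 0.40, and 21 of the 500 genes nearest in intensity lay lower than SPIN1. Its measurement rests on 1 feature. Of its relatives, SPIN2A stood at -1.09 (-0.77 with the pseudocount) and SPIN2B at 0.43, although these genes are close copies whose probes may not separate them. SPIN3 stood at 0.57, SPIN4 at 0.25 and the SPIN1 partner SPINDOC at 0.53. SPIN2A, SPIN3 and SPIN4 were among the dimmer genes.

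The comparison of the arrays asks which transcripts differ between drug-resistant cells given SPIN1 siRNA and those given the control. The outstanding difference among bright transcripts was that of MMP1, the interstitial collagenase, at 17948 in the siRNA array against 2967 in the control array, 6.05-fold higher. SERPINB2, an inhibitor of plasminogen activators, was 3.87-fold higher (3705 against 956). The cytokine IL6 was 3.51-fold higher (582 against 166), and the matricellular protein gene CCN2, formerly CTGF, was 2.96-fold higher (1554 against 525). MMP1, SERPINB2 and CCN2 each exceeded all 500 genes nearest in intensity, and IL6 exceeded 498 of them.

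Among the brighter genes, 114 were 2-fold or more higher and 64 were 2-fold or more lower in the siRNA array. This split depended on scaling: it was 90 and 76 after centring on the median of all genes and 84 and 87 after removal of the intensity trend. Besides MMP1, SERPINB2 and IL6, the 12 highest were the neural and sensory transcription factor gene POU4F3 (log2 difference 2.33), the mitochondrial calcium uptake gene MICU2 (2.28), the ubiquitin and ribosomal fusion gene UBA52 (2.12), ARMCX2 (2.05), DAW1 (2.04), the zinc finger gene ZNF18 (2.01), the transcription factor gene ZIC2 (1.97), KIAA0586 (1.81) and the syntaxin gene STX3 (1.80). All 12 rest on 1 feature each. The control intensities of POU4F3, ARMCX2, ZNF18, DAW1, MICU2, IL6, ZIC2 and STX3, from 124.3 to 213, were under the 95th percentile of olfactory receptor genes. That of UBA52, 274 (8.10 on the log2 scale), was just above it. The mean log2 intensity of 79 ribosomal protein genes was 13.4, and whether the UBA52 feature measures its transcript well could not be examined.

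The 12 lowest of the brighter genes were led by VXN, at 126 against 1436, and by the keratin-associated protein gene KRTAP6-2, 4.65-fold lower at 333 against 1549. They also held 4 olfactory receptor genes, OR4N2 (-2.08), OR5K2 (-1.75), OR51F2 (-1.72) and OR8J1 (-1.69). The others were the cerebral cavernous malformation gene CCM2 (-1.78), the carboxyl ester lipase gene CEL (-1.66), MTRES1 (-1.66), MTUS1 (-1.54), VCF2 (-1.51) and SOBP (-1.51). Each rests on 1 feature. The siRNA intensities of 10 of the 12, all except KRTAP6-2 and CCM2, lay from 126 to 202 and so under the olfactory receptor 95th percentile, which leaves the sizes and order of their differences uncertain. Olfactory receptor genes as a family were lower in the siRNA array, with a median of -0.53 over 281 genes, 81 of them 2-fold or more lower and 13 2-fold or more higher, and 57 keratin-associated protein genes had a median of -0.67.

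**Figure D1:**
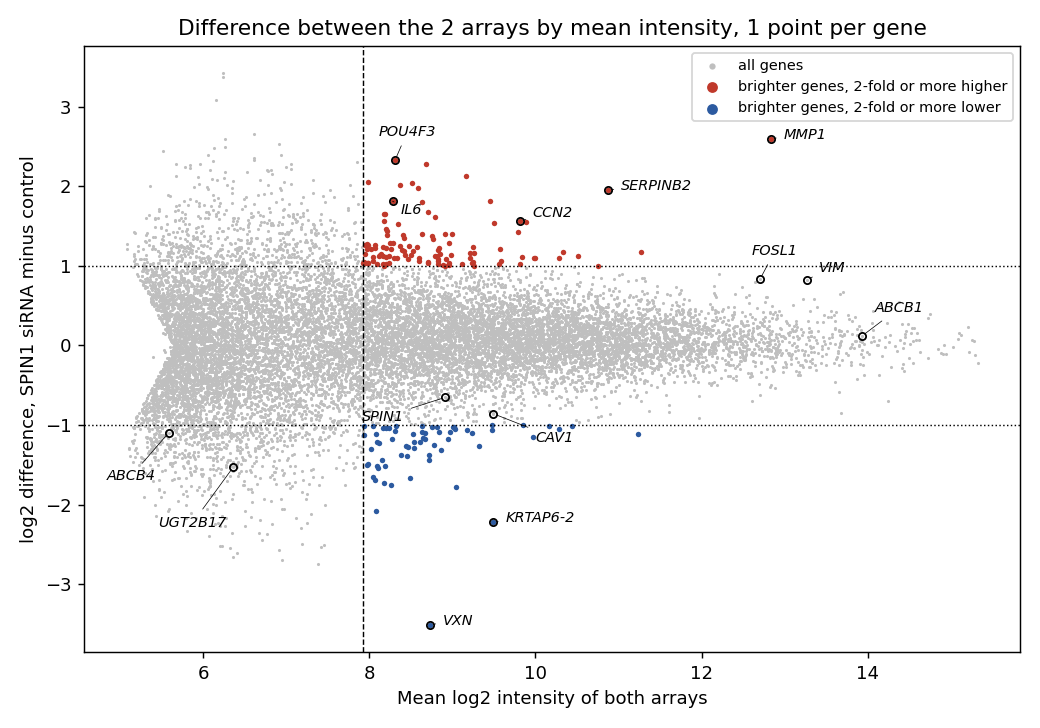
Each point is 1 named gene, with its mean log2 intensity over both arrays on the x axis and its log2 difference (SPIN1 siRNA minus control) on the y axis; the dashed line marks the lower limit of the brighter genes and the dotted lines 2-fold. The scatter narrows with intensity, and MMP1, at a difference of 2.60, stands apart from genes of like brightness.

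Mesenchymal genes were higher on balance in the siRNA array. Of 24 measured, 14 lay above 0 and 3 were 2-fold or more higher, with none 2-fold lower. The list's median log2 difference was 0.27, at the 98.8th percentile of intensity-matched random lists. CCN2 stood at 1.57, VIM, the intermediate filament of mesenchymal cells, at 0.83 (13107 against 7388), SERPINE1, the plasminogen activator inhibitor, at 0.55, and the matricellular gene CCN1 at 0.51. VIM exceeded 498 of the 500 genes nearest in intensity. The other members past 2-fold, chosen after their values were seen, were THBS1 (1.06) and MMP14 (1.03), both dim. The transcription factor genes of epithelial-mesenchymal transition, also named after their values were seen, did not share a direction, with SNAI2 at 0.40 and ZEB1 at -0.33.

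Inflammatory and growth factor signalling genes included several of the higher transcripts. Of 27 NF-kB and inflammatory genes, 17 lay above 0 and 5 were 2-fold or more higher, with none 2-fold lower. The median was 0.25, at the 95.6th percentile and so inside the central 95% of random lists, but 0.02 at the 43rd percentile over the 5 members in the brightest 25% of genes. IL6 (1.81) and the chemokine gene CXCL2 (1.03) were past 2-fold among the brighter genes, where the adhesion molecule gene ICAM1 stood at 0.48 and NFKB1 at 0.37. The control intensities of IL6 and CXCL2 (171.7) were under the olfactory receptor 95th percentile, and CXCL2 stood at 0.78 with the pseudocount and 0.95 after removal of the intensity trend. The other 3 past 2-fold, chosen after their values were seen, were the chemokine genes CCL20 (1.79) and CXCL1 (1.37) and the prostaglandin synthase gene PTGS2 (1.63), all dim. PI3K/AKT and MAPK genes had a median of 0.23 over 30 genes, at the 95.9th percentile, which turned to -0.08 at the 14.7th percentile over the 7 members in the brightest 25% of genes. The AP-1 subunit gene FOSL1 was 1.79-fold higher at 8933 against 4995, ETV4 stood at 0.84, PIK3CA at 0.97 and the kinase gene AKT2 at -0.85. Of 35 interferon response genes, 2 were 2-fold higher and 2, both dim, were 2-fold lower, with a list median of 0.01 at the 28.7th percentile. MX2 stood at 1.12, IRF9 at 1.05 (0.96 after removal of the intensity trend and 0.79 with the pseudocount, with a control intensity of 169.6), HERC5 at 0.68 and the double-stranded RNA sensor EIF2AK2 at -0.62.

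**Figure D2:**
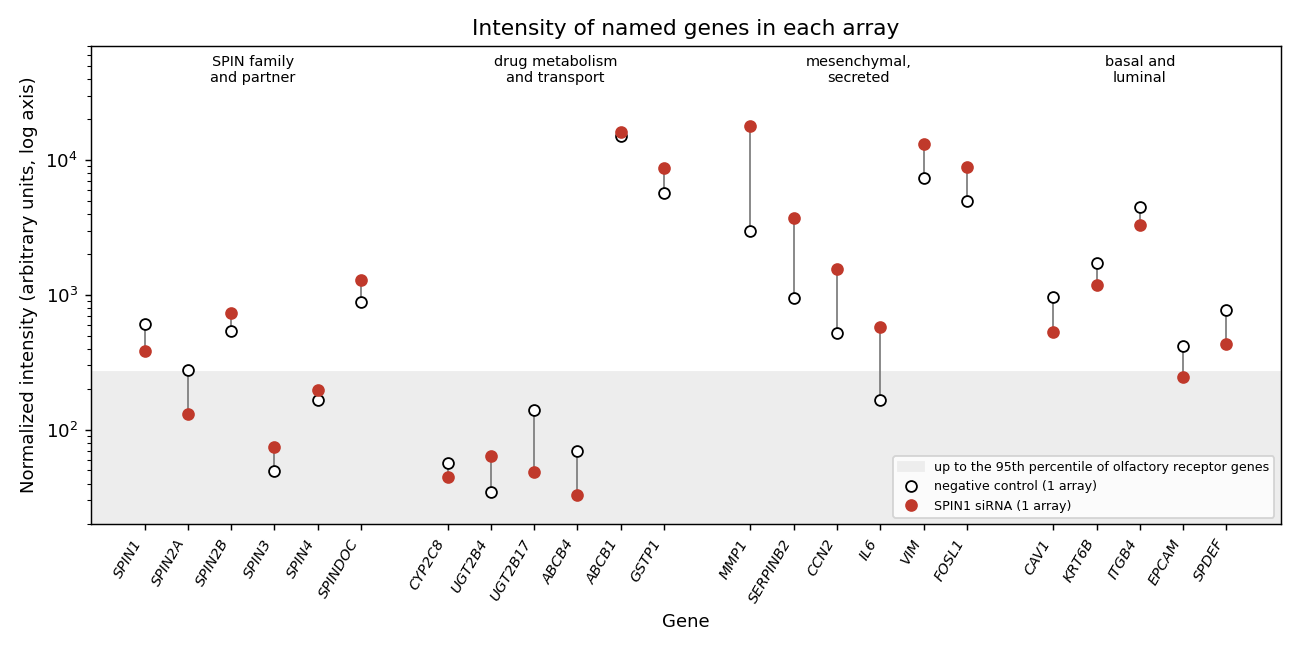
Normalized intensity (log axis) of named genes in the control array (open circles) and the siRNA array (filled circles), 1 array each; ABCB1 is shown for reference. The shaded band reaches to 269, the 95th percentile of olfactory receptor genes, and holds both values of CYP2C8, UGT2B4, UGT2B17 and ABCB4, while MMP1 lies at 2967 and 17948.

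Basal epithelial genes were lower on balance. Of 17 measured, 6 lay above 0 and 2, both dim, were 2-fold or more lower, with none 2-fold higher. The median was -0.24, at the 0.15th percentile of matched random lists. The caveolin gene CAV1 stood at -0.86, the keratin gene KRT6B at -0.55, the integrin gene ITGB4 at -0.44 over 3 features (-0.08 by its brightest feature) and the laminin gene LAMC2 at 0.50 over 2 features. With the brightest feature of each gene, or with the brighter members alone, the list lay inside the central 95%. Without its keratin genes the median of the other 11 members was -0.07, at the 15.7th percentile, and the 46 keratin genes on the array had a median of -0.37. Luminal and oestrogen response genes had a median of -0.05 and a mean of -0.17 over 21 genes, at the 19.2nd percentile. Of these, 9 lay above 0, 1 was 2-fold or more higher and 2 were lower, and all members past 2-fold were dim. The median was 0.03 by the brightest feature, and the difference between the basal and luminal lists was not tested. Among them the luminal transcription factor gene SPDEF stood at -0.84, the epithelial adhesion gene EPCAM at -0.77, FOXA1 at 0.80 and GATA3 at 0.49. The siRNA intensity of EPCAM (246) and the control intensities of FOXA1 (194) and GATA3 (244) were under the olfactory receptor 95th percentile.

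Drug metabolism and transport genes were of interest because the line is drug resistant. The drug efflux pump gene ABCB1 (P-glycoprotein, named after its values were seen) was among the bright transcripts and differed by 0.12 on the log2 scale (16222 in the siRNA array, 108.5% of control). Among 4 genes remembered from the study's publication, UGT2B17, a steroid glucuronosyltransferase, stood at -1.52 (48.6 against 139.8), ABCB4, a phospholipid transporter, at -1.09 (32.9 against 70.2), CYP2C8, a drug-oxidising cytochrome P450, at -0.33 (44.9 against 56.5) and UGT2B4 at 0.88 (63.7 against 34.5). Their median of -0.71 lay at the 5.67th percentile of matched random lists. All of these intensities fall under the olfactory receptor 95th percentile of 269, and the local spread there was 0.70 to 0.83. Of the 500 genes nearest in intensity, 12 lay lower than UGT2B17 and 27 lower than ABCB4. With the pseudocount UGT2B17 stood at -0.78, ABCB4 at -0.41 and the list median at -0.27. This list was probably chosen on these arrays and is not independent evidence of its direction. Genes with little reason to be active in this line were also lower. Their medians were -0.53 for olfactory receptor, -0.34 for leukocyte and -0.25 for liver genes. The leukocyte and liver lists lay inside the central 95%, and protocadherin genes stood at 0.13. Matching on intensity does not correct for such a shift. Whether the dim drug metabolism genes here and below follow it was not tested.

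Cytochrome P450 genes went both ways. Of 26 measured, 3 were 2-fold or more higher and 4 lower, and the median of -0.20 lay at the 8.46th percentile. With the 5 brighter members alone, a setting chosen after the data were seen, the median of -0.29 lay outside the central 95%, at the 2.36th percentile. CYP4A11, a fatty acid hydroxylase, was 2.41-fold lower at 411 against 988, below all 500 genes nearest in intensity. The other 6 past 2-fold were dim: CYP3A4 (2.28), CYP3A5 (2.13), CYP2C19 (1.21), CYP24A1 (-1.11), CYP2B6 (-1.10) and CYP2A13 (-1.07). With the pseudocount these stood at 1.01, 0.84, 0.59, -0.45, -0.53 and -0.47 in the same order, so that CYP3A4 alone of the 6 was still past 2-fold. The brighter members CYP2S1 (-0.32), CYP1A2 (-0.29) and CYP26B1 (-0.24) lay below 0. Close sequence between CYP3A4 and CYP3A5 leaves open whether their features measure separate transcripts.

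Conjugation, efflux and uptake genes had medians within the central 95% of random lists. Phase II enzymes had a median of 0.00 (-0.0031) over 37 genes at the 33.9th percentile, with none 2-fold higher and with GSTA1 (-2.05) and UGT2B17 past 2-fold lower, both dim and within 2-fold with the pseudocount, at -0.94 and -0.78. GSTP1, the main glutathione transferase of many tumour cells, was bright and 1.53-fold higher (8750 against 5726), above 490 of its 500 neighbours in intensity, and TPMT stood at 0.49, GSTT1 at 0.40 and GSTT2 at 0.40. Anthracycline reductases and other phase I enzymes had a median of -0.03 and a mean of 0.00 (0.0022) over 33 genes, at the 17.9th percentile. XDH stood at 0.77, NDUFS3 at 0.67, ALDH1A3 at 0.55, AKR1B10 at 0.39 and the dim FMO4 at -1.48 (-0.56 with the pseudocount). Over 16 ABC efflux genes the median was 0.10, at the 65.3rd percentile, and -0.12 over the brightest 25% of genes, with ABCC6 at 1.14 (0.55 with the pseudocount) and ABCB4 at -1.09 as the members past 2-fold, and ABCB8 at 0.65, ABCC4 at 0.53, ABCB6 at 0.33 and ABCC2 at -0.19. Over 19 SLC uptake genes it was -0.25, at the 7.36th percentile, with the nucleoside carrier genes SLC29A2 at 1.26 and SLC28A3 at -1.05 (0.97 and -0.49 with the pseudocount), the carnitine carrier gene SLC22A5 at 0.86, SLCO3A1 at -0.44 and SLCO4A1 at -0.36. Xenobiotic receptors had a median of -0.05 over 15 genes at the 21.9th percentile, with NR1H3 at 0.54, CEBPB at 0.43 and ARNT at 0.24. NRF2 targets had a median of 0.00 (0.00064) over 23 genes at the 23.9th percentile, with TXN at -0.52, GSR at 0.43 and SLC7A11 at 0.43.

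Genes of RNA polymerase I and ribosome biogenesis, a process in which SPIN1 has been placed, were higher on balance. Of 31 measured, 25 lay above 0 and 1 was 2-fold or more higher. The median was 0.20, at the 98.3rd percentile. POLR1A, the largest subunit of the polymerase, stood at 0.65, BYSL at 0.53, TAF1C at 0.46 and NOP16 at 0.43. The member past 2-fold, named after its value was seen, was the dim POLR1B (1.57). Over the brightest 25% of genes the list lay inside the central 95%. Cytosolic ribosomal protein genes had a median of 0.08 over 40 genes at the 80.2nd percentile, with RPL15 at 0.52, RPS5 at 0.43, RPL18 at 0.34 and RPL10 at 0.33.

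Clustered histone genes were lower on balance. Of 20 measured, 4 lay above 0, and the median of -0.19 lay at the 1.03rd percentile, though no member was 2-fold different. H2AC6 stood at -0.58, H2BC11 at -0.36, H2AC8 at -0.31 and H2BC12 at 0.30. Most replication-dependent histone transcripts lack a poly(A) tail, and the cDNA was primed with oligo-dT. These histone genes lack introns, and the coding sequences of olfactory receptor genes, whose median was -0.53, are also free of them. Whether this relates to the lower histone values was not tested. With the brighter members alone, or over the brightest 25% of genes, the histone list lay inside the central 95%.

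Cell cycle, repair and death genes had medians inside the central 95% of random lists. Mitotic genes had a median of 0.12 over 40 genes at the 84.1st percentile, with HMMR at 1.04 (0.95 after removal of the intensity trend and 0.79 with the pseudocount), NCAPG at 0.82, MAD2L1 at 0.74 and BUB1 at 0.64. DNA replication genes had a median of 0.05 over 38 genes at the 42.3rd percentile, with cyclin E1 (CCNE1) at 1.17, ORC1 at 0.85, PRIM1 at 0.60 and POLE2 at 0.57. DNA repair genes had a median of 0.04 over 35 genes at the 41.9th percentile, with RAD54L at 1.08 (0.93 with the pseudocount), TOP2B at 0.47, XPA at 0.47 and RAD51C at 0.44 over 2 features. Targets of p53 had a median of 0.08 over 27 genes at the 62.0th percentile, with CCNG1 at 1.22, GADD45A at 0.89, GDF15 at -0.66 and PLK2 at 0.60. Apoptosis genes had a median of -0.02 but a mean of 0.11 over 31 genes, at the 16.3rd percentile, with the adaptor gene FADD at 1.33, the pro-apoptotic gene BAD at 1.24, BIRC2 at 0.64 and CYCS at 0.56.

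Wnt targets and genes of GDNF and RET signalling, pathways that have been tied to SPIN1, also lay inside the central 95%. Of 27 Wnt genes, 5 were 2-fold higher, all dim, and 2 lower, of which only NOTUM was among the brighter genes. The list median was 0.11 at the 74.6th percentile and turned to -0.07 over the brightest 25% of genes. The Wnt deacylase gene NOTUM stood at -1.21, TCF7L1 at 0.57, MYC at -0.32 and CD44 at 0.31. The GDNF and RET genes had a median of -0.04 and a mean of 0.01 over 8 genes at the 38.2nd percentile, with MAZ at -0.35 and GFRA1 at 0.55 over 2 features. By the brightest feature GFRA1 stood at 0.18 and the list median at -0.17. Chromatin regulators had a median of 0.06 over 28 genes at the 53rd percentile, with PRMT6 at 0.83, EZH1 at 0.57, HDAC2 at 0.57 and PRMT2 at 0.47. The RNA interference machinery had a median of 0.17 over 11 genes at the 78.0th percentile, with XPO5 at 0.57, TARBP2 at 0.37 over 3 features (0.22 by its brightest feature), AGO2 at 0.25 and TNRC6A at 0.17.

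Stress, metabolic and reference genes had medians inside the central 95%, and several list medians close to 0, those of the housekeeping and interferon genes among them, changed sign with the scaling. Unfolded protein response genes had a median of 0.16 over 28 genes at the 88.7th percentile, with HERPUD1 at 0.56, HSP90B1 at 0.55, ATF6 at -0.53 and PDIA4 at -0.47. Heat shock genes had a median of 0.05 over 17 genes at the 54.3rd percentile, with HSPA6 at 0.43, HSPH1 at 0.37, HSPB1 at -0.36 and HSPA1A at 0.33. Cholesterol synthesis genes had a median of 0.06 over 25 genes at the 52.3rd percentile, with squalene epoxidase (SQLE) at 1.10, above 499 of its 500 neighbours in intensity, HMGCR at 0.70, MSMO1 at 0.55 and CYP51A1 at -0.78. Hypoxia and glycolysis genes had a median of 0.05 over 31 genes at the 48.8th percentile, with SLC2A3 at 1.00 (0.92 after removal of the intensity trend and 0.79 with the pseudocount), the bright NDRG1 at -0.75 (2397 against 4030), PFKFB3 at 0.60 and KDM3A at -0.45. Housekeeping genes had a median of 0.02 over 16 genes at the 35.8th percentile, with GUSB at 0.40, YWHAZ at -0.34, POLR2A at -0.34 and TBP at 0.27. Markers of cell types that the culture should lack were mostly dim, except CD68 among the leukocyte genes and FGG and C3 among the liver genes. Leukocyte genes had a median of -0.34 over 16 genes at the 8.83rd percentile, with CD68 at -0.04, and liver genes a median of -0.25 over 14 genes at the 12.4th percentile, with FGG at -0.39 over 2 features (-0.14 by its brightest feature) and C3 at -0.19. The SPIN family and its partner had a median of 0.34 over 6 genes at the 89.3rd percentile, a list that contains SPIN1 itself.

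**Figure D3:**
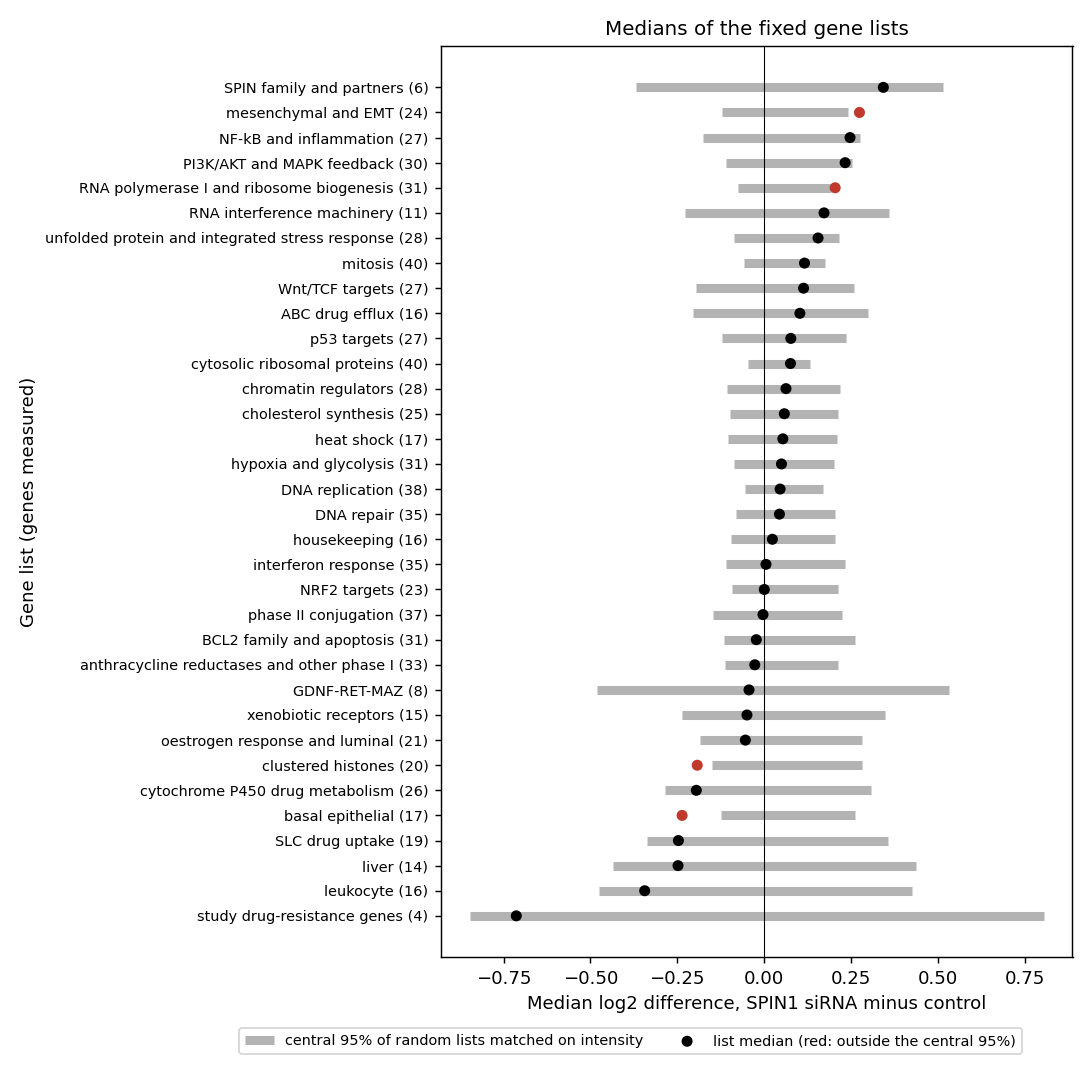
Median log2 difference (SPIN1 siRNA minus control) of each of the 34 fixed gene lists (points, with the number of genes measured), against the central 95% of 10000 random lists matched on intensity (grey bars). The mesenchymal (0.27), RNA polymerase I (0.20), histone (-0.19) and basal epithelial (-0.24) lists, in red, lie outside their bars.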

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

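Tests chosen after the data were seen were the olfactory receptor filter and the list medians over brighter members alone. The SPIN1 difference ranged from -0.73 to -0.56 over the 6 alternatives. The 114 higher and 64 lower genes became 785 and 750 with no signal filter, 14 and 6 over the brightest 25% of genes, 629 and 315 at 1.5-fold, 16 and 9 at 3-fold, 289 and 391 when features replaced genes, and 53 and 29 with a pseudocount. The share of higher among these genes moved from 64.0% to 54.2% after centring, 49.1% after lowess, 49.4% after a second quantile normalization, 51.1% with no filter and 42.5% over features. The move over features came with the unnamed ones, since named features gave 141 and 82 and unnamed features 148 and 309; why these were more often lower was not tested. Keeping genes above the 95th percentile of olfactory receptor intensity gave 97 and 57. The number of lists outside the central 95% was 4, became 2 over the brightest 25%, where fewer members remain, and was 3 or 4 otherwise. Over brighter members alone the cytochrome P450 list came to lie outside, at the 2.36th percentile, and the histone and basal lists inside. Against random lists not matched on intensity it was again 4, but these were the remembered drug genes (0.99th percentile), cytochrome P450 (1.57th), SLC uptake (1.76th) and leukocyte (0.56th) lists. Of 294 list medians under the alternatives, 35 changed sign, none of them of a list outside the central 95%; most had medians close to 0, but the PI3K, Wnt and ABC efflux medians also turned over the brightest 25%. No named gene changed sign in 483 values with the brightest feature, lowess or a pseudocount, but of 52 named genes past 2-fold the pseudocount left 18 within 2-fold and lowess 5. Of the 18, the dim drug metabolism and transport genes lost the most, since the pseudocount shrinks differences of dim genes by construction. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal limits the dimmer genes, where 2-fold differences are common in both directions. The filter on all genes left the list medians as they were, since lists already used all measured members.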

Other observations

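The explanations weighed here were tested after the patterns were seen, and the tests of intensity noise, the intensity trend, dim features and feature error were also formulated after their results were known. Among brighter genes that the report does not name, the 5 on each side farthest from their neighbours in units of local spread were taken, a choice made after the data were seen. On the higher side the mitochondrial ribosomal protein gene MRPL48 was 2.93-fold higher, the proteasome ATPase gene PSMC1 2.25-fold, FBXO5, an inhibitor of the anaphase-promoting complex, 2.89-fold, PSG9 2.68-fold and the lysosomal protease gene LGMN 2.26-fold. On the lower side the keratin-associated protein genes KRTAP21-2 and KRTAP19-1 were 2.16-fold and 2.21-fold lower, CCDC122 1.88-fold, the ciliary gene BBS5 1.79-fold and the SUMO protease gene SENP3 2.01-fold lower. Each of these genes rests on 1 feature. Unnamed features, outside the gene comparisons, had 148 higher and 309 lower among 10811 at or above the median feature intensity, against 141 and 82 among 8553 named ones.

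Olfactory receptor genes were lower in the siRNA array, with a median of -0.53 over 281 genes, 210 of them below 0. Noise or a trend of dim features is argued against, since none of 10000 random lists matched on intensity had a median as low (0th percentile), and so is a block of features with neighbouring accessions, since 298 other features of the same blocks had a median of -0.012. A lower signal of short single-exon families may contribute and stays open: 100 genes of 4 other families had a pooled median of -0.56, but 57 of them were keratin-associated protein genes (-0.67), and the 14 taste receptor genes (-0.43) lay inside the central 95% of random lists while the 11 interferon alpha genes (-0.71) lay outside it. The remaining family, 18 protocadherin alpha and beta genes, did not share the lower signal. Its median was 0.13, at the 76.2nd percentile of random lists, with 6 genes below 0. The prediction had been a median below 0 in each family, so the test was undecided. The families were taken as short and single-exon without a check of exon number. The protocadherin genes, the alpha genes above all, may not be of this kind, so their median does not count against the explanation. Dim genes were also grouped by genomic span, after the olfactory receptor genes and the other gene families examined were left out, which left 6806. The 269 shortest had a median of -0.11 and the 4104 longest 0.08, with -0.02 and -0.07 between. Among these remaining genes a short span alone thus came with a smaller difference than -0.53, and exon number was not tested. Beta defensin (-0.30) and late cornified envelope genes (-0.32) lay inside the central 95%, and keratin genes (-0.37) outside it. Probe composition and gene silencing could not be examined with these data, and no biological explanation was tested.

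Mesenchymal genes were higher and basal epithelial genes lower in the siRNA array. A smooth intensity trend between the arrays was already met by the matching of random lists on intensity. Under it the basal list lay at the 0.15th percentile and the mesenchymal list at the 98.8th. After the trend was removed these lists lay at the 0.08th and the 98.4th. The matching made this outcome nearly certain in advance, so it adds no support. Noise of dim features does not account for the mesenchymal part, since over brighter members alone that list lay at the 99.5th percentile, but it stays open for the basal list, which lay inside the central 95% in that setting (8.45th percentile) and outside it over the brightest 25% of genes (0.18th). The basal part may also come from the keratin genes, since without them the list lay at the 15.7th percentile, and keratins and keratin-associated proteins share the lower signal of the olfactory receptors. For the mesenchymal part an effect of the SPIN1 siRNA, an off-target effect and a chance difference between the cultures stay open and untested with 1 array per group.

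The 2-fold differences of the brighter genes may be in large part error of single features. Among 587 genes with 2 or more features at or above the intensity limit of the brighter genes, taken as 1 pair per gene, the log2 differences of the features correlated with r = 0.24 (Spearman 0.23) across genes, and 352 pairs shared a sign (exact 95% interval of the share 55.9% to 64.0%). Of 14 pairs with 1 or both features past 2-fold, 10 shared a sign and 1 was past 2-fold the same way in both. Features of a gene can also measure different transcript variants, which lowers the correlation without error.

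A hypothesis from MMP1, SERPINB2, CCN2 and IL6 was that other targets of the transcription factor AP-1 or of YAP and TEAD were higher too. The 27 AP-1 targets measured had a median of 0.03 at the 37.9th percentile of matched random lists, and the 21 YAP and TEAD targets, which include NT5E (1.68, named after its value was seen), a median of 0.19 at the 92.1st percentile. Neither list lay outside the central 95%, so these arrays do not show a broad rise of either group, and with 1 array per group a smaller one may be missed.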
